A study of Homo sapiens and Mus musculus with 21 samples.

How the data were processed

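RNA from frozen mouse caecum was sequenced with Smart-seq2, a full-length cDNA protocol, in 21 samples of 7 groups with 3 replicates each: SW480 with dnLEF1 or Mock, SW620 with dnLEF1, Mock, LRP6KO or Cas9, and PBS without tumour cells. The deposited tables hold TPM per gene, transcript abundances scaled by length and library total, 1 table for human genes in the 18 xenograft samples and 1 for mouse genes in all 21 samples. Per the submitters' processing notes, reads were trimmed with Trimmomatic 0.35, aligned with Bowtie 1.2 and quantified with RSEM 1.2.31 against hg38 and mm10. Each library summed to 1000000 TPM within each table. The values are therefore relative to the organism's own transcripts and keep no depth, so no counting interval or detection floor is given, and the planned check of the human share of each library could not be run.

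Human identifiers (58381) were joined to symbols by identifier, and 58261 were found in GENCODE release 29. The 45 second copies of pseudoautosomal genes on chromosome Y were 0 throughout and were left out. None of the 54146 mouse identifiers was in a name table, so the 20 mouse gene lists prepared could not be tested and mouse genes are given by identifier.

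Genes with at least 1 TPM in at least 3 libraries were tested (22981 human, 19672 mouse). The test was limma 3.58.1 in R 4.3.3 with an intensity trend on log2(TPM + 1), with a mean per group and all groups of a table in the fit, which pools the spread over groups. P-values were adjusted by Benjamini and Hochberg within each of 11 comparisons, 7 in human and 4 in mouse genes, and 0.05 was the threshold. A comparison of changes is the difference of 2 contrasts in the same fit. Gene lists, 15 in human genes with 226 of 257 members tested, were compared with all other genes by camera with a preset correlation of 0.01 between genes, adjusted over the lists within a comparison. Camera with an estimated correlation and fry were run beside it. The lists covered Wnt targets, noncanonical Wnt genes, mesenchymal, epithelial, invasion and matrix genes, glycolysis, oxidative phosphorylation, proliferation, intestinal differentiation, hypoxia, interferon, YAP targets, TGF-beta and BMP genes, immediate-early and stress genes, and stroma genes in the human table. The stroma list holds genes of fibroblasts, vessels, leukocytes and muscle, which a carcinoma line should lack and mouse reads could bring.

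Genes were named by rule. In the comparisons of modified with control tumours these were the 8 largest changes each way, and 4 in the other human comparisons, among genes with a symbol, an adjusted p under 0.05, at least 5 TPM in the higher group and no overlap between groups. Where none passed, the 3 genes each way with the smallest p were named. Added to these were up to 4 members per list with the smallest p, and LEF1, LRP6, AXIN2 and LGR5, and 2 mouse identifiers each way. The groups, comparisons, test, naming rule, lists and the first set of alternatives were fixed before the data were examined. The windows along chromosomes were added later, as were the alternatives named as such with the results that depend on processing.

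Windows of 10 Mb with at least 10 genes of mean TPM of at least 5 (263 windows, 9291 genes) were compared with 20000 random draws of as many genes, adjusted over the windows. Neighbouring windows were counted against 10000 random placements within the same chromosomes, and the trend with base composition was removed in 20 bins. Calculations around the fits used Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures matplotlib 3.10.9.

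The test was tried on simulated data, in 10 rounds with 100 genes changed 2-fold and 100 changed 4-fold. Changed genes were drawn from those with a mean TPM of at least 5. With a spread shared by all groups, 3.4% to 5.1% of calls were false. With the spread of each line kept, 40.9% of the calls were false for SW480 dnLEF1 against Mock, 12.1% for the difference between lines, 12% for SW620 Mock against SW480 Mock and 3.4% to 5.1% for the other human comparisons. In mouse genes they were 8.1% for control xenografts against PBS, 22.1% for SW480 dnLEF1, 12.7% for SW620 dnLEF1 and 10.8% for LRP6KO. All 10 planted lists of 20 genes shifted by 0.5 were found in each human comparison, and 0.7% to 2.9% of unchanged lists were called. Simulated genes were independent, so the correlation within lists was not tested. Windows were simulated in 20 rounds for LRP6KO against Cas9 only. All 100 planted window shifts of 0.4 were found there, and 14.5% of called windows had not been planted.

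The alternatives chosen beforehand were a pseudocount of 0.1, no filter on low values, median-ratio scaling, only the groups of a comparison in the fit, array weights, the replicate number as a block, and each library left out in turn. Permutations of the sample labels were run for every count, 10 splits for 3 against 3 and 100 drawn splits for larger designs. Nothing was left out of the human or mouse tables apart from the pseudoautosomal copies and genes under the filter.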

Results

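RNA was sequenced from the caecum of NSG mice, an immunodeficient strain, 28 days after human colon carcinoma cells or phosphate-buffered saline (PBS) were injected into the caecum wall. The 21 samples fall into 7 groups of 3. SW480 and SW620 are established colorectal carcinoma lines from a primary tumour and a metastasis of the same patient. Both carried dnLEF1, a dominant negative form of the Wnt transcription factor LEF1, or a mock construct (Mock). SW620 was also given CRISPR reagents against the Wnt co-receptor LRP6 and sorted for low LRP6 protein (LRP6KO), or Cas9 alone (Cas9). PBS mice received no tumour cells. Human transcripts of the 18 xenograft samples and mouse transcripts of all 21 samples were given in separate tables. Values are TPM, transcript abundances scaled to sum to 1000000 per library in each table, so the sequencing depth and the human share of a library are unknown. The human table held 24665 to 34709 genes above 0 per library, and 24350 to 38985 mouse genes were above 0. The study design speaks of biological triplicates, but the sample labels do not state that each came from its own animal, so the p-values measure spread between these samples. Folds are differences of log2(TPM + 1), which understate the change of genes at low levels.

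The first principal component of the human table held 40.6% of the variance and separated SW480 from SW620. The second held 9.7% and set SW480 Mock replicate 2 (34709 genes above 0) and SW620 LRP6KO replicate 1 (34114 genes) apart from the rest, with SW480 Mock replicate 3 at the opposite end (53.3, against -69 for SW480 Mock replicate 2). Mean correlation with the other libraries of its group was 0.917 to 0.931 for SW480 libraries and 0.940 to 0.966 for SW620 libraries. Transcripts of mitochondrial coding genes made up 4.87% to 6.06% of human TPM in SW620 dnLEF1 libraries and 4.73% to 5.71% in SW620 Cas9, against 3.75% to 4.03% in SW620 Mock and 3.93% to 4.20% in SW620 LRP6KO. The most abundant gene of a library held 4.73% to 5.95% in SW620 dnLEF1 and 3.26% to 5.76% in SW620 Cas9, against 1.97% to 2.97% in SW620 Mock. These library differences run along with the SW620 comparisons against Mock and cannot be separated from the groups. The mitochondrial share also separates LRP6KO from Cas9 without overlap, so the same holds for that comparison. The median SD between replicates was 0.345 log2 units in SW480 dnLEF1 and Mock and 0.224 in SW620 dnLEF1 and Mock.

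What does dnLEF1 change in SW480 tumours? LEF1 (ENSG00000138795.9, chromosome 4, 108047545 to 108168956 in GRCh38) rose from 11.05 ± 5.21 TPM in Mock to 65.52 ± 29.34 TPM in dnLEF1 (SD, n = 3 each), a log2 change of 2.50 with a standard error of 0.33 and an adjusted p of 8.51e-04. Gene-level TPM does not separate the introduced form from the cell's own LEF1. AXIN2 (ENSG00000168646.12, chromosome 17, 65528563 to 65561647), a feedback inhibitor switched on by Wnt signalling, fell from 57.24 ± 7.85 to 29.33 ± 3.43 TPM (SD, n = 3 each; log2 change -0.94, SE 0.19, adjusted p 0.0147). DKK1, a secreted Wnt antagonist, fell by 1.10 on the log2 scale (SE 0.24, adjusted p 0.0221). LRP6 (log2 change 0.24, SE 0.28, adjusted p 0.758) and the stem-cell receptor LGR5 (0.15 ± 0.21 against 0.13 ± 0.12 TPM, adjusted p 1) were not called.

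SMOC2, a secreted matricellular protein gene (ENSG00000112562.18, chromosome 6, 168441151 to 168673445), rose from 0.42 ± 0.09 to 25.7 ± 7.19 TPM (SD, n = 3 each; log2 change 4.20, SE 0.22, adjusted p 3.86e-08). KRT75, an epithelial keratin gene (ENSG00000170454.5, chromosome 12, 52424070 to 52434525), fell from 196.07 ± 40.7 to 6.18 ± 2.74 TPM (SD, n = 3 each; log2 change -4.82, SE 0.26, adjusted p 3.86e-08). The other large rises were in the microRNA host gene MIR205HG (log2 change 3.94), the soluble collagen receptor LAIR2 (3.48), LYPD1 (3.38) and PRAP1 (2.66), with standard errors of 0.36 to 0.43 and adjusted p of 0.00282 or lower. TAB3-AS1 (2.87) and GUSBP14 (2.63) also rose, but their values are uncertain, since the former lies antisense to another gene and the latter is a pseudogene. HM13-AS1, also antisense, was listed at 0 in all Mock libraries and at 5.20 ± 1.18 TPM in dnLEF1 (SD, n = 3). The other large falls were in the cystatin gene CST1 (log2 change -3.11), CD8B (-3.06), SCGB2A1 (-2.68), SMCO2 (-2.66), the keratin KRT13 (-2.65), the kinase SYK (-2.61) and LY6G6D (-2.57), with standard errors of 0.23 to 0.52 and adjusted p of 0.0128 or lower. In each of these 16 genes the 3 dnLEF1 and 3 Mock libraries did not overlap, which the naming rule requires.

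Among members of the prepared lists, single genes were called in both directions. The matrix genes FN1 (log2 change 1.75, SE 0.37, adjusted p 0.02) and TNC (1.02, SE 0.19, adjusted p 0.00964) rose, as did the protease MMP9 (1.89, SE 0.42, adjusted p 0.0267) and the protease inhibitor TIMP1 (1.15, SE 0.17, adjusted p 0.0015). The hypoxia-induced carbonic anhydrase CA9 rose from 122 ± 72.1 to 409 ± 36.8 TPM (SD, n = 3 each; adjusted p 0.00171), and ANKRD37 rose by 1.46 (SE 0.23, adjusted p 0.00325). The intestinal transcription factor CDX2 fell from 40.6 ± 6.05 to 12.7 ± 3.11 TPM (SD, n = 3 each; adjusted p 0.00696), and ID2, a target of BMP signalling, from 105 ± 10.5 to 37.9 ± 4.42 TPM (adjusted p 6.67e-05). Falls were also called in KRT19 (-0.66), the laminin gene LAMB3 (-0.98), the lactate transporter SLC16A1 (-1.15), the thymidylate synthase TYMS (-0.57), AMOTL2 (-1.21) and ANKRD1 (-0.95), and rises in S100A4 (0.63), ID3 (1.07) and DUSP1 (0.72), with adjusted p from 0.00743 to 0.0488.

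By limma with all 6 xenograft groups in the fit, 512 of 22981 genes passed an adjusted p of 0.05 in SW480, 311 higher and 201 lower with dnLEF1. With each library scaled by its median ratio, 233 were higher and 252 lower, so that the higher share went from 60.7% to 48%. The groups did not overlap in 2697 genes (11.7%), where chance gives 10%. In simulated data in which each line kept its own spread, 40.9% of the calls of this comparison were false. With only the SW480 dnLEF1 and Mock libraries in the fit, 29 genes passed, and LEF1 had an adjusted p of 0.087 (1e-04 to 0.087 over its alternatives). Of the 35 called genes named here other than LEF1, 13 passed in that fit: SMOC2, MIR205HG, LAIR2, LYPD1, TAB3-AS1, PRAP1, HM13-AS1, KRT75, CST1, CD8B, KRT13, LY6G6D and ID2. The count was 1214 without dnLEF1 replicate 1, 258 without dnLEF1 replicate 2, 274 without dnLEF1 replicate 3 and 302 without Mock replicate 1.

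**Figure D1:**
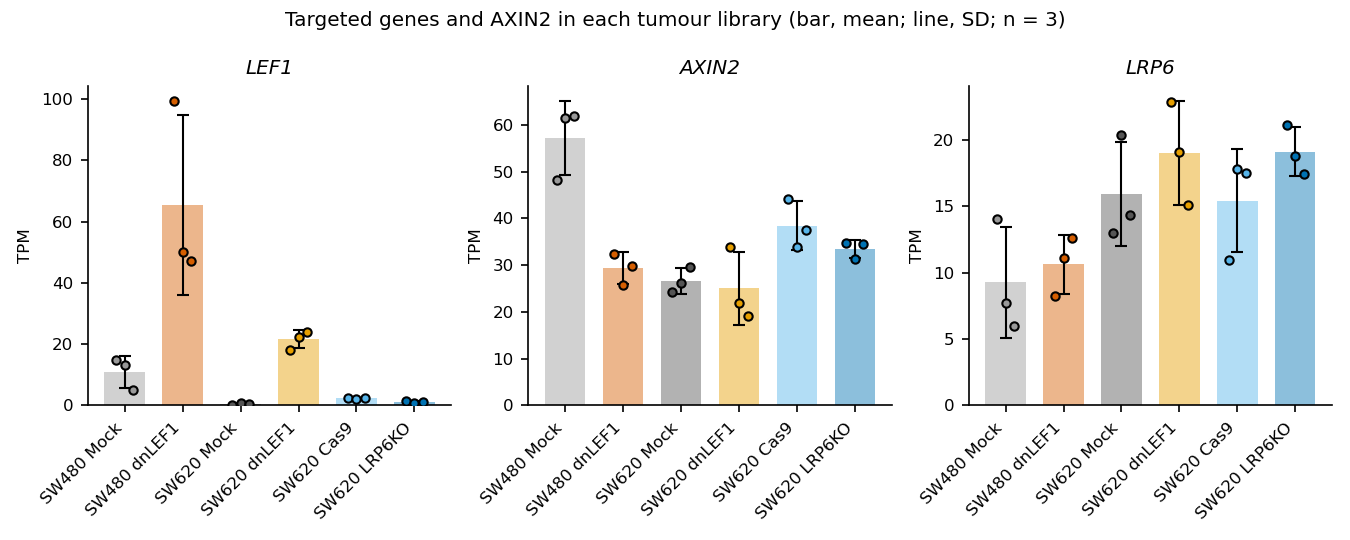
Each point is the TPM of LEF1, AXIN2 or LRP6 in a tumour library, with the mean of each group as a bar and its SD as a line (n = 3). LEF1 is higher with dnLEF1 in both lines, AXIN2 lower with dnLEF1 in SW480, and LRP6 not lower in the sorted LRP6KO cells (19.12 against 15.42 TPM in Cas9).

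Over whole lists in SW480, the 15 hypoxia genes had a median log2 change of 0.81, with 13 above 0, 2 risen over all genes and 7 risen when adjusted over the list alone (camera adjusted p 4.03e-06, 0.466 with an estimated correlation). All 20 proliferation genes lay below 0 (median -0.29), with 1 fallen over all genes and 3 when adjusted over the list alone (camera adjusted p 1.44e-06, 0.466 with an estimated correlation). Glycolysis genes had a median of 0.36, with 1 fallen over all genes, and 7 risen and 1 fallen when adjusted over the list alone (camera adjusted p 0.00625, 0.581 estimated). The mesenchymal list had a median of 0.40, with 2 risen over all genes and 3 adjusted over the list alone (camera adjusted p 0.0191, 0.551 estimated), and the interferon list 0.36 with no gene called either way (camera adjusted p 0.033, 0.581 estimated). Among the 20 Wnt targets, 13 lay below 0 (median -0.21), with 2 fallen over all genes, and 1 risen and 3 fallen when adjusted over the list alone (camera adjusted p 0.0642, 0.551 estimated). The remaining 9 lists had camera adjusted p from 0.221 to 0.977. Their medians were 0.16 for noncanonical Wnt genes, 0.06 for epithelial genes, 0.05 for oxidative phosphorylation, 0.11 for immediate-early and stress genes and 0.06 for stroma genes. Median and test differed in sign for intestinal differentiation (median 0.14, mean -0.15, test down), TGF-beta and BMP genes (0.06, -0.14, down), YAP targets (0.02, -0.02, down) and invasion and matrix genes (-0.04, 0.12, up).

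What does dnLEF1 change in SW620 tumours? LEF1 rose from 0.56 ± 0.25 to 21.58 ± 2.98 TPM (SD, n = 3 each; log2 change 3.86, SE 0.33, adjusted p 7.48e-05). AXIN2 (25.05 ± 7.86 against 26.71 ± 2.77 TPM, log2 change -0.13, SE 0.19, adjusted p 0.897), LRP6 (log2 change 0.25, adjusted p 0.852) and LGR5 (7.69 ± 0.58 against 6.53 ± 2.48 TPM, adjusted p 0.841) were not called. The DNA repair gene MGMT rose from 0.32 ± 0.45 to 7.07 ± 0.69 TPM (SD, n = 3 each; log2 change 2.66, SE 0.24, adjusted p 8.84e-05). Rises were also called in LHFPL6 (2.51), MLIP (2.35), the semaphorin and VEGF co-receptor NRP1 (2.00), the GABA receptor subunit GABRA2 (1.79), the secretory-pathway disulfide isomerase AGR2 (1.76) and the secretogranin SCG2 (1.60), with adjusted p from 7.98e-04 to 0.0286. The endoplasmic reticulum calcium channel ITPR2 fell from 39.1 ± 2.17 to 4.79 ± 0.90 TPM (SD, n = 3 each; log2 change -2.80, SE 0.32, adjusted p 7.98e-04). BCL2L15 (-1.66), the cytokine receptor IL20RA (-1.64), TMX4 (-1.62), the centrosomal gene KIZ (-1.57), the chemokine CXCL6 (-1.50), TAFAZZIN (-1.44) and the actin-severing gene GSN (-1.43) also fell, with adjusted p from 4.8e-04 to 0.041. TAFAZZIN, a cardiolipin-remodelling gene, lies on chromosome X at 154411518 to 154421726, inside a block of neighbouring genes that shifted together between the SW620 groups. The simple-epithelial keratin KRT19 fell from 2352.75 ± 221 to 1263 ± 57.7 TPM (SD, n = 3 each; log2 change -0.89, SE 0.13, adjusted p 0.006). KRT19 also lay below Mock in groups without dnLEF1, at 1609 ± 217 TPM in Cas9 and 1748 ± 49.95 TPM in LRP6KO. Cas9 differed from the same Mock libraries by -0.55 (SE 0.13, limma adjusted p 0.462).

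By limma, 38 of 22981 genes passed in SW620, 13 higher and 25 lower with dnLEF1. With median-ratio scaling 20 were higher and 19 lower, so that the higher share went from 34.2% to 51.3%. The groups did not overlap in 20.9% of genes, where chance gives 10%. With only the SW620 dnLEF1 and Mock libraries in the fit, 120 genes passed, including every gene called above. The count was 22 without dnLEF1 replicate 1, 22 without dnLEF1 replicate 2, 17 without dnLEF1 replicate 3, 25 without Mock replicate 1 and 22 without Mock replicate 2.

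**Figure D2:**
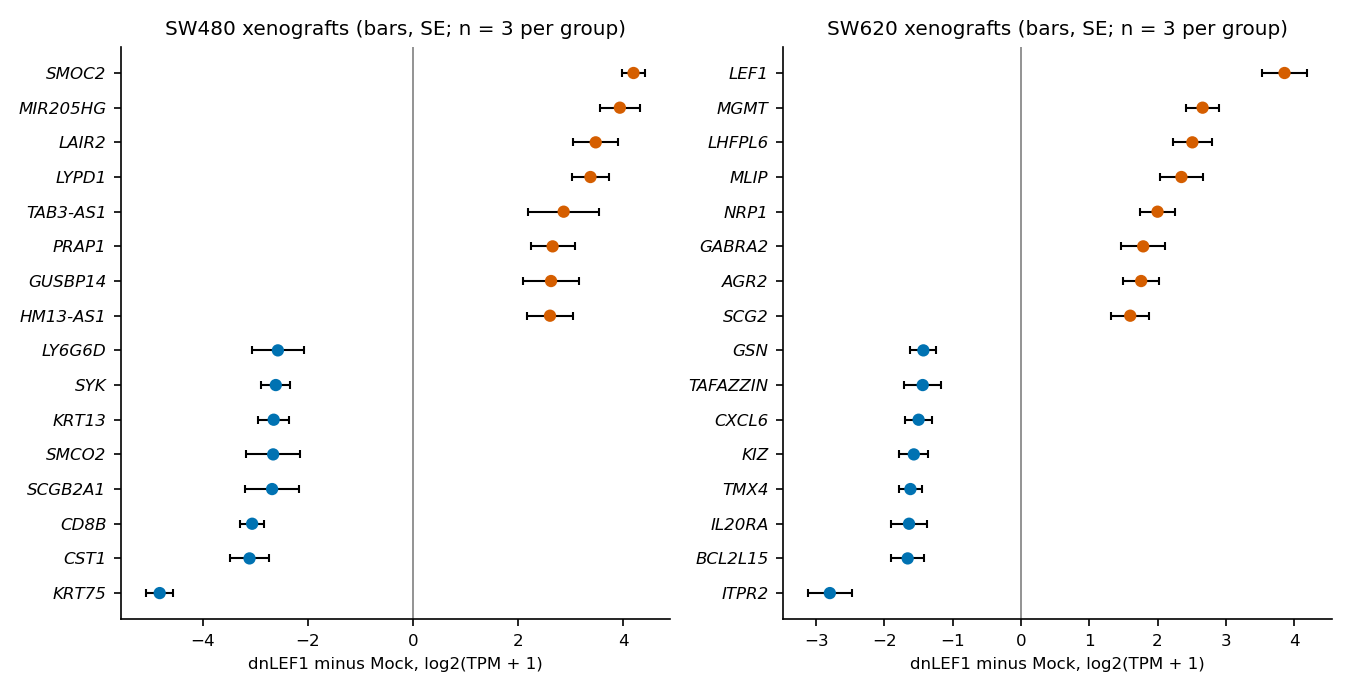
Points are log2 changes of the named genes in SW480 and in SW620 (dnLEF1 against Mock) and lines their standard errors (n = 3 libraries per group). The panels show the 8 largest rises and 8 largest falls by the naming rule in each line, and no gene is in both. HM13-AS1 was at 0 in all Mock libraries, so its point is no fold.

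Over whole lists in SW620, epithelial genes had a median log2 change of -0.49, with 2 of 16 above 0, 1 fallen over all genes (KRT19), and 2 risen and 8 fallen when adjusted over the list alone (camera adjusted p 7.95e-06, 0.126 with an estimated correlation). All 13 interferon genes lay below 0 (median -0.48), with no gene called over all genes and 3 fallen when adjusted over the list alone (camera adjusted p 7.95e-06, 0.223 estimated). Hypoxia genes had a median of -0.43 with 2 fallen when adjusted over the list alone (camera adjusted p 0.0104, 0.472 estimated), glycolysis genes a median of -0.24 (0.021, 0.472 estimated) and intestinal differentiation genes -0.47 (0.043, 0.223 estimated). The 20 Wnt targets had a median of 0.05, with 2 risen and 1 fallen when adjusted over the list alone (camera up, adjusted p 0.0293, 0.293 estimated). Cas9, without dnLEF1, also had higher Wnt targets and lower hypoxia and glycolysis genes against the same Mock libraries. A deviation of the Mock libraries alone would give these directions in both comparisons. The other 9 lists had camera adjusted p from 0.0658 to 0.754. Median and test differed in sign for TGF-beta and BMP genes (-0.10, up), and median and mean for noncanonical Wnt genes (0.08 and -0.02).

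Do the dnLEF1 changes differ between the lines? The difference of the 2 changes, SW620 minus SW480, was largest among genes with clear names in KRT75 (4.63, SE 0.37, adjusted p 1.72e-05), MGMT (2.91, SE 0.34) and LHFPL6 (2.72, SE 0.41) upward, and in SMOC2 (-3.85, SE 0.32, adjusted p 1.72e-05), LAIR2 (-3.46, SE 0.61), PRAP1 (-3.45, SE 0.59) and MIR205HG (-3.38, SE 0.54) downward. KRT75 was near 0 in every SW620 group, with means of 0.29 to 0.47 TPM. SMOC2 was already at 15.7 to 22.5 TPM in all SW620 groups. RN7SL546P had the largest difference (5.59, SE 1.08, adjusted p 0.0239), but it is a 7SL pseudogene with near-identical copies, so its value is uncertain. Among list members, DKK1 (2.02, adjusted p 0.00952) and ID2 (1.60, adjusted p 0.00251) differed upward, and CA9 (-2.42, adjusted p 0.00915), ANKRD37 (-1.97, adjusted p 0.00952), TIMP1 (-1.43, adjusted p 0.00921), ELF3 (-1.39, adjusted p 0.0199) and S100A4 (-0.94, adjusted p 0.0251) downward. By limma, 165 genes differed, 41 upward and 124 downward, and with median-ratio scaling 60 and 73 (higher share 24.8% to 45.1%). Scaling moved the median over all genes from -0.17 to -0.01. In simulated data with a spread per line, 12.1% of the calls of this comparison were false. The count was 801, 107 and 81 without SW480 dnLEF1 replicates 1, 2 and 3, and 271 without SW480 Mock replicate 2. It was 85, 94 and 82 without SW620 dnLEF1 replicates 1, 2 and 3, and 109, 66 and 84 without SW620 Mock replicates 1, 2 and 3.

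All 15 hypoxia genes had a negative difference between the lines (median -1.10), with 2 called over all genes and 10 when adjusted over the list alone (camera adjusted p 2.19e-07, 0.186 with an estimated correlation). In SW620 the hypoxia list was about as low in Cas9 against the same Mock libraries (median -0.41) as in dnLEF1 against Mock (median -0.43). Both comparisons use the same Mock libraries, so a deviation of these alone would also give both values. All 13 interferon genes also had a negative difference (median -0.92), with 7 called when adjusted over the list alone (camera adjusted p 1.06e-05, 0.186 estimated). Glycolysis (median -0.56, camera adjusted p 2.25e-04, 0.377 estimated) and epithelial genes (-0.49, 0.00156, 0.186 estimated) differed downward, and Wnt targets (0.27, 0.00342, 0.186 estimated) and proliferation genes (0.18, 2.25e-04, 0.377 estimated) upward. For glycolysis genes and Wnt targets, SW620 Cas9 against Mock also went in the direction of SW620 dnLEF1 against Mock.

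**Figure D3:**
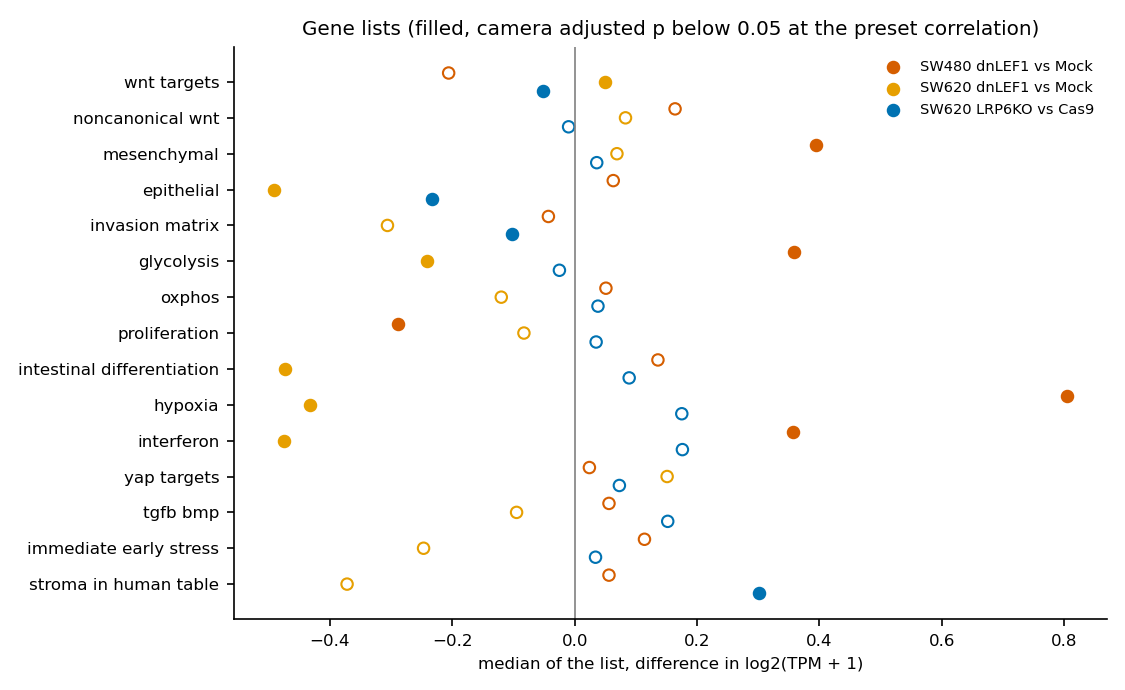
Points are the median log2 change of each of the 15 gene lists in the 3 comparisons of modified against control tumours, filled where the camera test with its preset correlation gave an adjusted p under 0.05. The hypoxia list lies at 0.81 in SW480 and at -0.43 in SW620 with dnLEF1.

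How do LRP6KO tumours of SW620 differ from Cas9 tumours? LRP6 itself (ENSG00000070018.8, chromosome 12, 12116025 to 12267012) was at 19.12 ± 1.86 TPM in LRP6KO and 15.42 ± 3.89 TPM in Cas9 (SD, n = 3 each; log2 change 0.32, SE 0.28, adjusted p 1). The cells had been sorted on protein, which was not measured here. The transcript therefore does not show whether these tumours lacked LRP6, and exchanged LRP6KO and Cas9 labels cannot be excluded from it, which holds for every LRP6KO value given. AXIN2 was at 33.5 ± 1.97 against 38.5 ± 5.25 TPM and LGR5 at 6.20 ± 1.99 against 7.39 ± 0.66 TPM, neither called (adjusted p 1). The genes with the smallest p were EVA1A (log2 difference 1.01, SE 0.20, adjusted p 0.544), ZNF346 (0.95, adjusted p 0.685) and PLAAT3 (0.55, adjusted p 0.685) upward, and DKK1 (11.1 ± 2.09 against 27.4 ± 3.00 TPM, log2 difference -1.24, SE 0.24, adjusted p 0.544) and DNAJC15 (-0.96, adjusted p 0.544) downward. The small nucleolar RNA gene SNORA79B was listed at 0 in all LRP6KO libraries and at 5.95 ± 1.36 TPM in Cas9 (adjusted p 0.0805). By limma, 0 of 22981 genes passed, 766 had an unadjusted p under 0.05, and the groups did not overlap in 9.7% of genes, where chance gives 10%. The count was 10 with only the LRP6KO and Cas9 libraries in the fit, 1 with array weights, and 0 with another pseudocount, scaling or filter and without any single library. In simulated data of this comparison, 93.2% of 4-fold changes and 50.5% of 2-fold changes were recovered. The changed genes all had a mean TPM of at least 5, so recovery at lower levels, or with fewer changed genes, is unknown.

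Epithelial genes were lower in LRP6KO as a list, with 2 of 16 above 0 and a median log2 difference of -0.23, led by CLDN3 (-0.79) and ESRP1 (-0.68), but no member was called over all genes or adjusted over the list alone (camera adjusted p 6.38e-06, 0.119 with an estimated correlation). CLDN3 was at 7.31 ± 0.77 TPM in LRP6KO, 13.62 ± 3.31 in Cas9 and 7.21 ± 0.99 in Mock, so Cas9 was the group apart. ESRP1 was at 2.73 ± 0.58, 4.94 ± 0.49 and 5.23 ± 0.84 TPM in these groups, with LRP6KO apart. Invasion and matrix genes (median -0.10, camera adjusted p 0.0321, 0.262 estimated) and Wnt targets (median -0.05, camera adjusted p 0.048, 0.545 estimated) were lower, with 1 Wnt target fallen when adjusted over the list alone. Wnt targets were also higher in the same Cas9 libraries than in Mock. A deviation of the Cas9 libraries alone would therefore also give lower Wnt targets in LRP6KO. Stroma genes were higher (median 0.30, camera adjusted p 0.048, 0.731 estimated). Carcinoma cells should lack these genes, and mouse reads could bring them, which was not tested here. Their smallest p lay with PECAM1, at 4.86 ± 1.2 TPM in LRP6KO and 1.66 ± 0.61 TPM in Cas9 (SD, n = 3 each). Without the 2 libraries with most genes above 0, which include LRP6KO replicate 1, the invasion and matrix, Wnt target and stroma lists had adjusted p of 0.072, 0.0818 and 0.309. The remaining 11 lists had camera adjusted p from 0.459 to 0.973. Median and test differed in sign for oxidative phosphorylation (0.04, down) and intestinal differentiation (0.09, down).

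Do LRP6KO and dnLEF1 act differently in SW620? Each change was taken against its own control, LRP6KO minus dnLEF1. The differences therefore also hold the difference between the Cas9 and Mock controls. TAFAZZIN lay lower in Cas9 than in Mock (log2 difference -1.03, SE 0.27, limma adjusted p 0.563). LEF1 was at 2.38 ± 0.17 TPM in Cas9 and 0.56 ± 0.25 TPM in Mock, against 21.58 ± 2.98 TPM in dnLEF1 (SD, n = 3 each). LEF1 (-4.50, SE 0.47, adjusted p 0.00111), MLIP (-3.61, SE 0.44, adjusted p 0.00519), LHFPL6 (-2.77, SE 0.41, adjusted p 0.0159) and DKK1 (-2.15, SE 0.34, adjusted p 0.0238) differed downward. TAFAZZIN (2.32, SE 0.38), the chaperone gene CLU (2.12, SE 0.31), BCL2L15 (2.05, SE 0.34) and EVA1A (1.76, SE 0.28) differed upward, with adjusted p of 0.0154 to 0.0262. SNORA79B (adjusted p 0.0344) was listed at 0 in every LRP6KO and every Mock library. By limma, 16 genes differed, 10 upward and 6 downward. With median-ratio scaling 4 and 5 did (higher share 62.5% to 44.4%), and the median over all genes moved from 0.19 to 0.07. All 13 interferon genes had a positive difference (median 0.70, 1 called when adjusted over the list alone; camera adjusted p 1.59e-04, 0.39 estimated). Stroma (0.72, 0.00955, 0.603 estimated) and hypoxia genes (0.57, 0.0114, 0.617 estimated) also differed upward, and Wnt targets downward (-0.10, 0.00955, 0.39 estimated). For the stroma list, mouse reads in the human table were not tested as a source. Hypoxia genes were lower and Wnt targets higher in Cas9 than in Mock, which moves both differences in the directions seen. Of the 9 genes called here among those named by rule, 2 (LEF1 and MLIP) stayed past the threshold without any single library. The count was 3 and 6 without Cas9 replicates 1 and 2, 4 without dnLEF1 replicate 3, 4, 3 and 8 without LRP6KO replicates 1, 2 and 3, and 9, 5 and 6 without Mock replicates 1, 2 and 3.

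How do the control tumours of the lines differ? SW620 Mock was higher than SW480 Mock in the secreted trefoil factor TFF3 (492 ± 30.7 against 3.10 ± 4.65 TPM, log2 difference 7.57, SE 0.66, adjusted p 3.45e-07), CXCL6 (6.27, SE 0.20), the actin-bundling gene LCP1 (5.90, SE 0.26) and MFNG (5.85, SE 0.37). It was lower in the interferon-induced IFITM1 (1.29 ± 0.71 against 1224 ± 145 TPM, log2 difference -9.10, SE 0.24, adjusted p 9.7e-13), CST1 (-8.96, SE 0.37) and RN7SL1 (74.8 ± 128 against 8717 ± 7342 TPM, an uncertain multicopy RNA). MIR5096 was listed at 0 in SW620 Mock. WNT5A, a ligand of noncanonical Wnt signalling, was at 0.22 ± 0.35 TPM in SW620 and 14.7 ± 2.49 TPM in SW480 (log2 difference -3.70, SE 0.25, adjusted p 1.78e-08), and its receptor ROR2 was also lower (-3.33). The junction gene CLDN7 (-6.28), the intestinal factor CDX2 (-3.83), CD44 (-3.84) and the Wnt target APCDD1 (-4.99) were lower in SW620, and SOX4 (3.73), MMP7 (3.58), TNC (3.08) and VIM (1.12) higher. By limma, 5483 genes differed, 2508 higher and 2975 lower in SW620, and 35.4% of genes did not overlap, where chance gives 10%. Of 15 noncanonical Wnt genes, 8 were lower and none higher over all genes, and 10 lower when adjusted over the list alone (median -0.93, camera adjusted p 5.14e-04, 0.142 estimated). Invasion and matrix genes (median -1.29, 2 higher and 10 lower; camera adjusted p 0.00416, 0.142 estimated) and epithelial genes (-0.39, 1 higher and 4 lower; 0.0327, 0.548 estimated) were lower in SW620. Glycolysis (0.59, 9 higher and 1 lower; 2.14e-04, 0.548 estimated) and oxidative phosphorylation genes (0.52, 10 higher and none lower; 6.25e-04, 0.627 estimated) were higher. Wnt targets split, with 7 higher and 8 lower (median 0.66, mean -0.04, camera up, adjusted p 0.838).

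Do the control lines of SW620 differ? Between Cas9 and Mock, the smallest p lay with NGFR (16.8 against 5.23 TPM, log2 difference 1.54, SE 0.29, adjusted p 0.269), COG3 (1.17, SE 0.22, adjusted p 0.269), KRT86 (-1.09, SE 0.20, adjusted p 0.247), AMIGO2 (-0.97, SE 0.19, adjusted p 0.275) and FUNDC2 (-0.60, SE 0.12, adjusted p 0.275). FUNDC2 lies in the same block of chromosome X as TAFAZZIN. SNORA79B was listed at 0 in Mock and at 5.95 TPM in Cas9 (adjusted p 0.0594). By limma, 0 genes passed and 1154 had an unadjusted p under 0.05, 1 passed without Mock replicate 1, 8 with only these groups in the fit, 101 with array weights, 1 without the filter on low values and 1 among protein-coding genes alone. The groups did not overlap in 14.2% of genes, where chance gives 10%. Hypoxia genes were lower in Cas9 (median -0.41, 2 fallen when adjusted over the list alone; camera adjusted p 5.08e-05, 0.404 estimated), as were glycolysis (-0.14, 0.01, 0.607 estimated) and invasion and matrix genes (-0.12, 0.0458, 0.404 estimated). Wnt targets were higher (0.18, 0.00175, 0.376 estimated).

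Over windows of 10 Mb, neighbouring genes shifted together between SW620 groups. Of 263 windows, 25 departed from the rest of the genome with dnLEF1 against Mock (13 higher, 12 lower), 17 with LRP6KO against Cas9 (1 higher, 16 lower), 24 with Cas9 against Mock, and 0 with dnLEF1 in SW480. The end of the long arm of chromosome X (150 to 160 Mb, 47 genes) shifted by -0.35 with dnLEF1, 0.40 with LRP6KO and -0.42 in Cas9 against Mock. Its median per library, against the SW620 mean, was 0.06 to 0.19 in Mock and 0.15 to 0.31 in LRP6KO, and -0.22 to -0.12 in dnLEF1 and -0.34 to -0.17 in Cas9. On chromosome 7 (90 to 100 Mb, 46 genes) the Mock libraries lay at 0.20 to 0.30 and those of the other 3 groups at -0.17 to -0.05. These windows were examined after the results by gene had been seen. Other ways of dividing the same 6 libraries gave up to 20, 47 and 26 windows in these 3 SW620 comparisons.

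**Figure D4:**
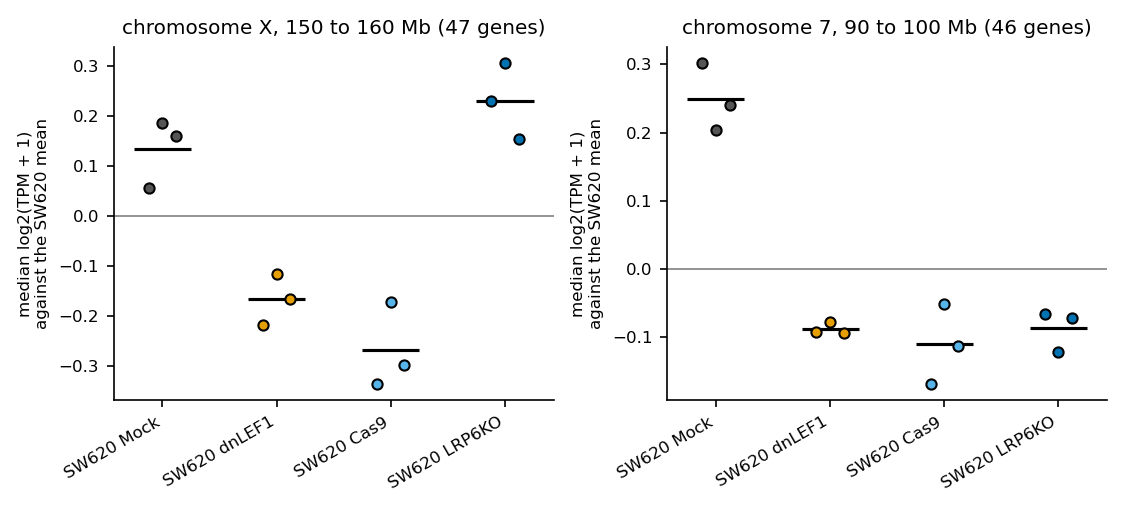
Each point is the median over genes of a window in a SW620 library, as log2 difference from the SW620 mean, for 150 to 160 Mb of chromosome X (47 genes) and 90 to 100 Mb of chromosome 7 (46 genes). On chromosome X, Mock and LRP6KO libraries lie above 0 and dnLEF1 and Cas9 libraries below, whereas on chromosome 7 the Mock libraries alone lie above 0.

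How does the host caecum respond to tumour cells? The mouse table gives identifiers that no annotation at hand could name. ENSMUSG00000029304.14 rose from 1.34 ± 0.48 TPM after PBS to 167.38 ± 104 in SW480 Mock, 85.48 ± 30.8 in SW620 Mock and 127.98 ± 40.1 in SW620 Cas9 (SD, n = 3 each; log2 change of the mean of these groups 5.64, SE 0.36, adjusted p 1.68e-07). ENSMUSG00000084817.3 was listed at 0 in all PBS libraries and at 28.09 ± 15.8, 62.24 ± 18.9 and 111.21 ± 61.1 TPM in those groups. Human reads counted as mouse genes could also give values in xenografts alone, so a host origin of this signal stays open. ENSMUSG00000080507.2 (97.36 ± 12.4 TPM after PBS, adjusted p 0.0169) and ENSMUSG00000078061.1 (216 ± 35.2 TPM after PBS, adjusted p 0.0169) fell, and both were no longer past the threshold when any of the 3 PBS libraries was left out. By limma, 1941 of 19672 genes passed, 1638 higher and 303 lower with tumour cells (84.4% higher), and with median-ratio scaling 1342 higher and 564 lower (70.4%). The count was 925 without PBS replicate 1 and 1233 without PBS replicate 3. Against PBS, SW480 Mock alone gave 465 genes, SW620 Mock 535 and SW620 Cas9 3128. On the first principal component of the mouse table (20.7% of the variance), the Cas9 libraries lay at 17.7 to 50.6 and the PBS, SW480 Mock and SW620 Mock libraries at -58.3 to 5.

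Does the host tissue change with the tumour's modification? In mouse genes, dnLEF1 against Mock gave 6 genes in SW480 tumours (4 higher, 2 lower; 1947 at an unadjusted p under 0.05) and 5 in SW620 tumours (3 higher, 2 lower; 2364). Scaling gave 4 and 4 in SW480 (higher share 66.7% to 50%), and 5 and 2 in SW620 (60% to 71.4%). The groups did not overlap in 13% and 17.4% of mouse genes, where chance gives 10%. The SW480 count was 46 without dnLEF1 replicate 1 and 2 without dnLEF1 replicate 2, dnLEF1 replicate 3, Mock replicate 1 or Mock replicate 2. The SW620 count was 0 without dnLEF1 replicate 2 or Mock replicate 1, 12 without dnLEF1 replicate 3, 2 without Mock replicate 2 and 143 without Mock replicate 3. LRP6KO against Cas9 gave 0 mouse genes by limma, with 910 at an unadjusted p under 0.05 and a smallest adjusted p of 0.449. That count was 4 with only these groups in the fit, 1 with a smaller pseudocount, 2 without Cas9 replicate 1, 1 without LRP6KO replicate 1 and 2 without LRP6KO replicate 3. The groups did not overlap in 9.4% of genes, where chance gives 10%.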

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

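The tests of chromosome segments, of dnLEF1 as the source of the blocks, of the shared spread, of the 2 libraries with most genes, and the splits of the samples were chosen after the results were seen. The tests of base composition and of a larger SW480 response were written before their results were seen, and the reading of the latter was made stricter after its value was known. Single outlying samples were not tested for within the groups of 3.

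The effect of dnLEF1 differed between the lines in 165 genes by a test of the difference itself (SW620 minus SW480). By gene, the log2 difference was 5.59 for RN7SL546P, 4.63 for KRT75, 2.91 for MGMT and 2.72 for LHFPL6, and it was -3.85 for SMOC2, -3.46 for LAIR2, -3.45 for PRAP1 and -3.38 for MIR205HG. By list, the median difference was 0.27 for Wnt targets and 0.18 for proliferation genes, and it was -1.1 for hypoxia, -0.92 for interferon, -0.56 for glycolysis and -0.49 for epithelial genes. Of 100 drawn splits, 1, the real one, gave as many genes, and the highest of the others gave 46. These splits exchange dnLEF1 and Mock labels within each line, so they test against no effect in either line. They cannot exclude chance as the source of a difference between equal effects. No list call held with an estimated correlation.

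The effect of LRP6KO differed from that of dnLEF1 in SW620 in 16 genes by a test of the difference itself (LRP6KO minus dnLEF1). Each effect has its own control, so a difference between Cas9 and Mock also enters these values. By gene, the log2 difference was 2.32 for TAFAZZIN, 2.12 for CLU, 2.05 for BCL2L15 and 1.76 for EVA1A, and it was -4.5 for LEF1, -3.61 for MLIP and -2.77 for LHFPL6. The fitted value for SNORA79B, -3.51, is no fold, since that gene is at 0 in all LRP6KO and Mock libraries. By list, the median difference was 0.7 for interferon, 0.72 for stroma, 0.57 for hypoxia genes and -0.1 for Wnt targets. None of these list calls held with an estimated correlation. Splits that exchange labels within each pair of groups test against no effect of either change, not against equal effects. Of 100 drawn splits, 2 gave at least 16 genes, a share under 0.05. The other gave 31, more than the real split. It exchanged all dnLEF1 and Mock labels and 2 of 3 labels each of LRP6KO and Cas9, so that it held the whole dnLEF1 change with its sign turned and a smaller part of the LRP6KO change. Of the 16 genes, 7 (43.8%) lie in windows that shifted between SW620 groups, which hold 14.8% of the genes tested. These windows were picked from changes in the same libraries, so the higher share is no independent support.

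More genes passed after dnLEF1 in SW480 (512) than in SW620 (38). The 2 libraries with most genes above 0 are argued against, since 590 SW480 genes passed without them. A shared spread that is too small for SW480 may contribute, since 29 SW480 genes passed with only the SW480 groups in the fit against 120 of SW620 in its own fit. That fit also finds less, with 4.4% of simulated 2-fold changes recovered in SW480 and 46% in SW620. A larger response of SW480 cannot be told apart from an equal one, because the covariance of log2 changes between disjoint library pairs was 0.0755 in SW480 (-0.047 to 0.202 over pairings) and 0.0956 in SW620. The splits of 3 against 3 are 10 in number, too few for a share under 0.05, with 512 genes in the real SW480 split against 112 in the highest other, and 38 against 2 in SW620.

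Blocks of neighbouring genes shifted together between SW620 groups, in 25 windows with dnLEF1 against Mock. Base composition is argued against, since all 25 remained without its trend, and so is dnLEF1 itself as the whole source, since 18 of them shifted in the same direction in Cas9 against Mock, which shares the Mock libraries. When unchanged groups sharing Mock libraries were simulated, 1 of 100 rounds gave 18 or more windows in common, 12 gave 25 or more windows (highest 63) and 2 gave 19 or more beside a window of the same direction (highest 25). Gain or loss of chromosome segments in derived lines is a candidate explanation, since 19 of the 25 lay next to another window of the same direction (at most 16 in random placements, p 0.0001, the smallest possible), but placements ignore differences between libraries that neighbouring genes share, no DNA was measured, and regulation over a whole domain stays open. Window counts alone do not separate groups, since other splits gave up to 20 windows against 25 with dnLEF1, 47 against 18 (in separate draws) with LRP6KO and 26 against 24 in Cas9.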

How the results depend on the processing

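The fits without the 2 libraries with most genes above 0, with the number of genes above 0 as a covariate, with protein-coding genes only, without shifted windows, and of each control group alone against PBS were chosen after seeing the data. No targeted gene or called named gene reversed its direction under the alternatives run. No list call did so under other processing or without the 2 libraries with most genes above 0. With fry and the estimated correlation the directions of lists were not compared. The majority direction of called genes did turn with median-ratio scaling, from 311 higher and 201 lower to 233 and 252 for SW480 dnLEF1, from 13 and 25 to 20 and 19 for SW620 dnLEF1, and from 10 and 6 to 4 and 5 for LRP6KO minus dnLEF1. Mouse SW480 dnLEF1 went from 4 and 2 to a tie of 4 and 4. Counts not given below stayed within 1.5 times their value.

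With a pseudocount of 0.1 the counts were 333 for SW480 dnLEF1, 21 for SW620 dnLEF1, and in mouse genes 15 for SW620 dnLEF1 and 1 for LRP6KO. Without the filter they were 1 for Cas9 against Mock, and in mouse genes 19 for SW480 and 3 for SW620 dnLEF1. Median-ratio scaling gave 9 for LRP6KO minus dnLEF1. With only the groups of a comparison in the fit, counts were 29 for SW480 dnLEF1, 120 for SW620 dnLEF1, 10 for LRP6KO, 43 for the difference between lines, 58 for LRP6KO minus dnLEF1, 8 for Cas9 against Mock, and in mouse genes 27 for SW620 dnLEF1 and 4 for LRP6KO. LEF1 in SW480 kept its log2 change of 2.50 there but had an adjusted p of 0.087 (1e-04 to 0.087 over its alternatives). That fit has fewer libraries and also takes the spread of SW480 alone, and for LEF1 these were not separated. In simulated SW480 data with a shared spread, 49.1% of 2-fold changes were recovered with all groups and 18.5% with only its own groups. With the spread of each line kept, the fit of its own groups recovered 4.4%. Array weights gave 261 for SW480 dnLEF1, 394 for SW620 dnLEF1, 1 for LRP6KO, 358 for the difference between lines, 209 for LRP6KO minus dnLEF1, 101 for Cas9 against Mock, and in mouse genes 56 for SW480 and 319 for SW620 dnLEF1. With weights, mouse SW480 dnLEF1 replicate 3 alone had a weight of 7.84. The replicate number as a block gave 417, 32 and 0 genes for the SW480 dnLEF1, SW620 dnLEF1 and LRP6KO comparisons, 144 and 19 for the differences, 5196 between lines, 0 for Cas9 against Mock, and 1753, 4, 6 and 0 in mouse genes, though numbers do not pair the samples. Apart from the shared spread, the cause of these changes was not tested.

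Without the 2 libraries with most genes, counts were 319 for the difference between lines, 4 for LRP6KO minus dnLEF1, and in mouse genes 2 for SW480 dnLEF1 and 2 for LRP6KO. The covariate gave 274 for the difference between lines and 2 for mouse SW620 dnLEF1. Protein-coding genes gave 280, 30 for LRP6KO minus dnLEF1 and 1 for Cas9 against Mock. Without shifted windows, 9 genes remained for LRP6KO minus dnLEF1. Against PBS, SW480 Mock alone gave 465, SW620 Mock 535 and SW620 Cas9 3128.

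Leaving out each library in turn gave 258 to 1214 genes for SW480 dnLEF1 (SW480 dnLEF1 replicate 1 gave the highest), 17 to 26 for SW620 dnLEF1, 0 to 0 for LRP6KO, 66 to 801 for the difference between lines, 3 to 13 for LRP6KO minus dnLEF1, 4228 to 5216 between lines and 0 to 1 for Cas9 against Mock. In mouse genes it gave 925 to 2298 for control xenografts against PBS, 2 to 46 for SW480 dnLEF1, 0 to 143 for SW620 dnLEF1 and 0 to 2 for LRP6KO. LEF1 ranged from 2.06 to 2.75 in SW480 and 3.73 to 3.97 in SW620, and LRP6 in LRP6KO from 0.10 to 0.43. Of called named genes, 20 of 35 for SW480 dnLEF1 and 10 of 16 for SW620 dnLEF1 (LEF1 aside in both) stayed past the threshold whichever library was left out, as did 12 of 15 and 2 of 9 for the differences, and 62 of 66 between lines. None of the list calls given with the results held with an estimated correlation, which took away 34 calls among the 105 list tests. With fry, 23 calls were lost and 3 gained. Scaling lost 1 and gained 2, the smaller pseudocount lost 3 and gained 1, and leaving out the 2 libraries with most genes lost 8 and gained 1. The depth of each library is unknown, so its effect on low genes could not be assessed, and the planned check of the human share of each library could not be run.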

Other observations

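Each xenograft group was also compared with PBS in mouse genes, after the joint comparison had been seen. Host genes past the threshold numbered 465 in SW480 Mock (395 higher, 70 lower) and 58 in SW480 dnLEF1 (56 higher, 2 lower). They numbered 535 in SW620 Mock (524 higher, 11 lower), 3128 in SW620 Cas9 (2554 higher, 574 lower), 2285 in SW620 dnLEF1 (1699 higher, 586 lower) and 2447 in SW620 LRP6KO (1952 higher, 495 lower). Directly compared, the hosts of SW620 Cas9 and SW620 Mock differed in 291 genes (210 higher, 81 lower in Cas9), those of SW620 LRP6KO and SW620 Mock in 10, and those of SW620 Mock and SW480 Mock in 14. The groups with the largest counts hold the mouse libraries that stand apart. On the first principal component (20.7% of the variance), SW620 Cas9, SW620 dnLEF1 and replicates 2 and 3 of SW620 LRP6KO lay at 17.7 to 53.4, and all other libraries at -58.3 to 5. Those 8 libraries had 24350 to 29598 mouse genes above 0 and the others 29434 to 38985. SW620 LRP6KO replicate 1 lay at -20.9 with 37521 genes above 0. The counts against PBS therefore also follow this structure of the libraries.

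The tests of composition and of the number of genes detected, and all splits of the samples, were chosen after the results were seen. Those of human reads, of shared calls and of the correlation between changes were written before, and the readings of the human-read and correlation tests were made stricter after their values were known.

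Most host genes past the threshold were higher with tumour cells than after PBS (1638 of 1941). Composition of the mouse table is argued against as the whole source, since 70.4% were still higher with median-ratio scaling. With the number of genes detected as a covariate, 1946 genes passed, so the total did not depend on it. That test counted calls and not their direction, so it leaves open whether the number of genes detected contributes to the higher share. Human reads counted as mouse genes stay open, since 2 genes were at 0 in all PBS libraries and at 1 TPM or more in all 18 xenografts (0 when any xenograft group took the place of PBS), and the test does not reach genes that the caecum already expresses. The labels do not state that each library came from its own animal, so splits of the libraries cannot exclude chance between animals. Of 100 drawn splits, 1, the real one, gave as many genes. The highest of the others gave 1216, with PBS replicate 2 exchanged for SW480 Mock replicate 3, and a host response to the tumour stays open.

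A shared response of both lines to dnLEF1 was tested on the overlap of calls. In the same direction, 5 genes were shared. LEF1 was higher in both (0.176 for independent lists, one-sided Fisher's exact p 0.162), and KRT23, TMEM45B, KRT19 and BCL2L15 were lower in both (0.219 for independent lists, one-sided Fisher's exact p 6.22e-05). TMX4 was called in opposite directions. Both sets of calls come from the same fit, with the spread of each gene pooled over groups. They are therefore not independent, which Fisher's test assumes, and LEF1 is the gene that was introduced. A small shared part could give the 4 lower genes. Of these, KRT19 was also lower in SW620 Cas9, without dnLEF1, against the same Mock libraries (log2 difference -0.55, SE 0.13). Across 10781 genes, which are not independent replicates, the log2 changes of the lines had a Pearson r of 0.028 and a Spearman rho of 0.004. Other splits of the SW620 dnLEF1 and Mock libraries gave absolute r of up to 0.085, so the correlation leaves the question open.

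A shared response to dnLEF1 and LRP6KO in SW620 was tested by the correlation of their log2 changes across 10781 genes, which are not independent replicates. Pearson's r was -0.135 and Spearman's rho -0.208, and other splits of the LRP6KO and Cas9 libraries gave absolute r of up to 0.293, so this test leaves the question open. Outside the shifted windows r was -0.095.

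Splits of 3 against 3 are 10 in number, and the smallest share they allow is 0.1, too few for a share under 0.05. For LRP6KO against Cas9 the real split gave 0 genes and the highest other 3, with all 10 splits giving at least as many, and Cas9 against Mock gave 0 and 3 likewise. SW620 Mock against SW480 Mock gave 5483 against 1. In mouse genes the values were 6 against 2 for SW480 dnLEF1, 5 against 2 for SW620 dnLEF1 and 0 against 3 for LRP6KO.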
